A study of Mus musculus with 2 samples.

How the data were processed

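Mouse brain cells sorted as CD11b high and CD45 low were captured with the 10x Genomics 3' v3 chemistry, 1 library per genotype, per the labels' protocols. Each library was deposited as raw UMI counts per gene and barcode; these counts come from Cell Ranger 3.1.0 after bcl2fastq with the GRCm38 build, per the submitters' processing notes, with no normalization. The gene annotation is not given in the sources used here; all 55450 gene identifiers and symbols in the files match GENCODE M21, which was used for coordinates. Of a symbol on several identifiers, the identifier with most counts was used. The labels do not state the depletion method, the animals per library or the floxed exons. Whether the fl/fl mice received tamoxifen is not known here. The genotype came from each sample's genotype label.

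Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept: 2826 of 3089 (91.5%) fl/fl and 2301 of 2607 (88.3%) cKO barcodes. Scrublet, run per library in scanpy 1.11.5, marked 2 (0.0708%) and 1 (0.0435%) of them, far below the share that droplet loading gives, so this caller did not work here and doublets largely remain. An added alternative removed the highest doublet scores at 0.8% per 1000 cells. The 2824 and 2300 kept cells had median depths of 9927.5 and 11728 UMIs. Counts per cell were scaled and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered by Leiden on 15 neighbours at resolution 0.8 (igraph 0.11.9, seed 1).

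A cluster was named after a class other than microglia when at least 3 of its fixed markers were detected in at least 25% of cells and 4-fold above the other cells (10 CPM added), with no other class equal among the top 10 genes by fold. It was named microglia-like when no other class had 3 such markers or more markers than microglia among the top 10 genes, and the 16 microglial markers were detected in at least 80% of cells on average. Clusters whose median depth was under 1/3 of their library's, with no marker among the top 10 genes, stayed unnamed. The marker lists of 18 classes were fixed beforehand and these thresholds were not.

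For each library, counts were summed over microglia-like cells (33132468 and 28749283 UMIs) and divided by the total to CPM, UMIs per 1000000 UMIs. Mitochondrial genes took 3.15% and 2.99% of these sums and ribosomal protein genes 14.4% and 14.0%. Ratios are log2 of cKO over fl/fl CPM after adding 1 CPM, which understates differences of low genes. Genes with a mean of at least 10 CPM counted as measured. A list's median was given with a counting interval from 1000 Poisson draws and with its percentile among 10000 random lists of the same size drawn within 20 expression bins. For list values by cluster, 7 clusters had at least 50 cells in each library. Cells were thinned without replacement to 5000 UMIs, the largest of 1000, 2000, 3000 and 5000 that kept at least 90% of microglia-like cells; those with UMIs of at least 3 of 12 G2/M or S genes were called positive. At the threshold of 3 genes lay 172 fl/fl and 97 cKO cells for G2/M and 157 and 120 for S.

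With 1 library per genotype no test was run, and no p-value or count of changed genes was drawn from cells. The sample groups, the 26 gene lists, the marker lists, the rule for named genes, the statistics and most alternatives were fixed before the data were examined. The named genes are Hk2, the other hexokinases and Cx3cr1; the 12 highest and 12 lowest ratios among genes with a mean of at least 50 CPM and Poisson intervals that do not overlap, leaving out mitochondrial, ribosomal protein, haemoglobin and sex genes and models named Gm or Rik; up to 4 members of each list with the largest ratio either way and its most abundant members; and the 12 G2/M and 12 S genes. Some genes, such as Apoe, Axl, Cd68 and Lpl, belong to more than 1 list.

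The steps on summed counts were checked on simulated data with the real genes and depths. With 50 genes each changed by 0.5, 0.8, 1.25 and 2-fold among 7816, median log2 ratios were -0.97, -0.31, 0.33 and 0.99, and 94.4% of exact intervals of 2000 unchanged genes held the true value. The simulated sums held Poisson counting error alone, so this checks the computation and not the spread between cells or animals. Alternatives were TMM scaling (edgeR 4.0.16 in R 4.3.3), CPM without mitochondrial and ribosomal protein genes, per-cell means, sums of thinned cells, 5 CPM added, other gene filters, cell filters, resolutions and doublet choices, and cells neither G2/M- nor S-positive. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.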

Results

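Single-cell 3' RNA profiles were collected from mouse brain cells sorted as CD11b high and CD45 low at day 3 of microglial repopulation. Hk2 encodes hexokinase 2, which phosphorylates glucose in the first step of glycolysis. There was 1 library from Hk2 fl/fl mice and 1 from Hk2 cKO mice, in which a tamoxifen-inducible Cre expressed from the Cx3cr1 locus targets the floxed gene. The fl/fl library held 3089 barcodes and 37476201 UMIs (median 9233 per barcode), and the cKO library held 2607 barcodes and 32896996 UMIs (median 10532). With 1 library per genotype, no difference below has a replicate check and none was tested. Intervals are 95% exact intervals (Poisson for counts, Clopper-Pearson for shares) and cover counting error only.

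Most of the sorted cells carried microglial markers in both libraries. Microglia-like cells made up 88.7% (87.5 to 89.8) of 2824 kept fl/fl cells and 88.0% (86.6 to 89.3) of 2300 kept cKO cells, within a gate that itself selects for them. The other named classes were small. Neutrophil-like cells, led by S100a8 and S100a9, were 2.80% (2.22 to 3.47) of fl/fl and 3.96% (3.20 to 4.84) of cKO cells. Monocyte-like cells, led by Plac8 and Ly6c2, were 2.80% (2.22 to 3.47) and 1.52% (1.06 to 2.11). Endothelial-like cells, led by Cldn5 and Flt1, were 1.84% (1.38 to 2.41) and 3.83% (3.08 to 4.69). Another 4 clusters stayed without a name. They were led by the osteoclast-type genes Ctsk, Acp5 and Mmp9 (cluster 7, 0.567% of fl/fl and 1.00% of cKO cells), by the RNA genes Gm26917 and Rn7sk (cluster 11, 1.10% and 0.0870%), by H2-Eb1, Cd74 and Cd209a (cluster 12, 1.74% and 1.35%) and by the choroid plexus gene Ttr (cluster 13, 0.460% and 0.217%). The thresholds for naming a cluster were set after the clusters had been seen. With a stricter cell filter the microglia-like share was 82.5% and 75.1%, because a microglial cluster then lost its name, and at a clustering resolution of 1.5 it was 83.7% and 85.2%, so the direction of this difference turned.

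The targeted gene was lower in the library labelled cKO. In microglia-like cells Hk2 (ENSMUSG00000000628, chromosome 6, 82725025 to 82774454, GRCm38) measured 166 CPM (162 to 170.5) in the fl/fl and 43.4 CPM (41.0 to 45.9) in the cKO library, a log2 ratio of -1.91, or 3.76-fold lower with 1 CPM added to each. An Hk2 UMI was seen in 75.5% (73.8 to 77.2) of 2505 fl/fl and 33.9% (31.9 to 36.0) of 2025 cKO microglia-like cells, and in 53.8% and 18.9% after thinning to 5000 UMIs. Hk2 was lower in each of the 7 microglia-like clusters, with log2 ratios from -2.34 to -1.31. It was also lower in neutrophil-like cells, at 141 (118 to 166) CPM against 78.3 CPM (103 UMIs), in monocyte-like cells, at 153 (126 to 184) against 77.4 (47.3 to 119.5) CPM, and in endothelial-like cells, at 113 (87.3 to 143) against 23.2 (14.9 to 34.6) CPM. These classes also hold microglial RNA. Cx3cr1 stood at 916 and 507 CPM in endothelial-like cells, but it is itself lower in the cKO library. The 4 microglial markers P2ry12, Tmem119, Siglech and Fcrls summed to 1748 CPM in fl/fl and 1645 CPM in cKO endothelial-like cells. In monocyte-like cells they summed to 1112 and 89.0 CPM, against 2690 and 2750 CPM in microglia-like cells. The monocyte-like values thus compare cells of unlike microglial content. Without UMIs of 4 microglial markers, Hk2 gave 0 UMIs in 8 and 20 endothelial-like cells, and its log2 ratio was -0.79 (-1.68 to 0.04) in monocyte-like and -0.80 (-1.60 to 0.02) in neutrophil-like cells; pooled over the 3 classes, whose mix differs between the libraries, it was -0.98 (-1.55 to -0.44; 82 and 107 cells). No class here is known to lack Hk2. As a measure of free RNA, the neutrophil gene S100a8 gave a UMI in 385 of 2505 fl/fl and 282 of 2025 cKO microglia-like cells (median depths 10193 and 12055 UMIs). The labels do not state which exons are floxed, and a 3' tag outside the deleted part checks nothing, so these levels need not report the deletion itself.

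**Figure D1:**
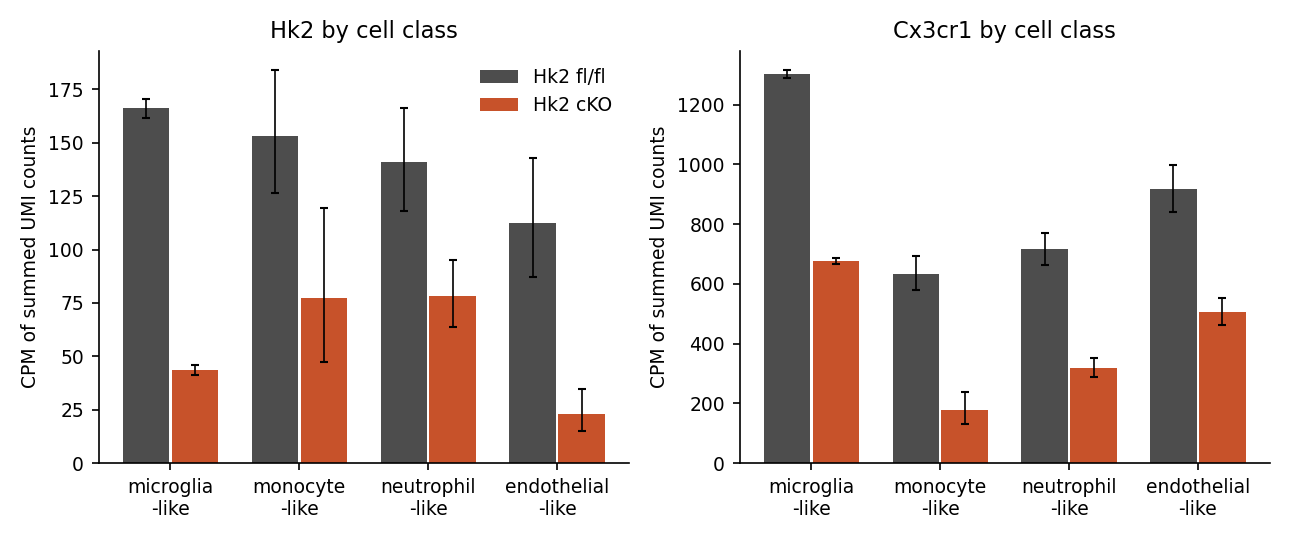
CPM of Hk2 (left) and Cx3cr1 (right) in counts summed over the cells of each named class, for the Hk2 fl/fl (grey) and Hk2 cKO (orange) libraries, with exact 95% Poisson intervals as bars. In microglia-like cells Hk2 stood at 166 against 43.4 CPM and Cx3cr1 at 1302 against 677 CPM.

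The other hexokinases were low or little different. Hk3 measured 46.5 (44.2 to 48.9) against 53.8 (51.2 to 56.6) CPM, a log2 ratio of 0.21, and Hk1 measured 11.4 (10.3 to 12.6) against 9.91 (8.80 to 11.1) CPM, with overlapping intervals. Hkdc1 gave 5 UMIs in the fl/fl and 11 in the cKO library. The median over the 3 measured hexokinases, Hk1, Hk3 and the targeted Hk2, was -0.18 (-0.38 to 0.01) (percentile 4.04). As the middle of 3 values this median is the ratio of Hk1 alone and shows no shift of the family. It ranged from -0.85 to 0.01 over 14 alternatives and turned sign under 1 of them. Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the fractalkine receptor gene whose locus carries the Cre driver, measured 1302 CPM (1289.8 to 1314) in the fl/fl and 677 CPM (667 to 686) in the cKO library, a log2 ratio of -0.94, and was lower in all 7 clusters. The fl/fl mice are described without this driver, so the lower Cx3cr1 level cannot be assigned to loss of Hk2.

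Glycolytic genes were slightly higher in the cKO sums over all microglia-like cells. Of 15 measured genes 11 were higher, with a median log2 ratio of 0.06 (0.02 to 0.09) at percentile 97.8 of 10000 random lists matched on expression, a description of these libraries only. Eno1, enolase 1, led with 263 (258 to 269) against 339.7 (333 to 347) CPM. Slc16a1, a lactate transporter gene, measured 12.0 (10.9 to 13.3) against 14.7 (13.3 to 16.1) CPM, and Ldhb 472 (465 to 479.7) against 532 (524 to 541) CPM. The most abundant member, Gapdh, was at 2661 (2644 to 2679) against 2634 (2615 to 2652) CPM, and Pkm at 802 (792 to 812) against 792 (781 to 802) CPM. The list was higher in 4 of the 7 clusters and lower in 3. Its direction depended on which fl/fl cells were compared: for 1435 cKO cells with UMIs of Gm28438, a nuclear copy of mt-Nd3, and none of mt-Nd3, groups made after the values of this pair were seen, the median was -0.10 (-0.15 to -0.01; 10 of 15 lower) against 305 fl/fl cells of the same kind and 0.08 (0.04 to 0.12) against 870 with mt-Nd3 alone. Of 9 measured genes of the HIF target list 7 were higher, with a median of 0.07 (0.02 to 0.13) at percentile 98.5. Among them was Hif1a, the gene of a HIF subunit itself rather than a target, at 63.4 (60.7 to 66.2) against 72.7 (69.6 to 75.8) CPM. Mxi1 was lower at 37.7 (35.6 to 39.8) against 31.3 (29.3 to 33.4) CPM.

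Most oxidative and other metabolic lists lay close to the bulk of genes, whose median log2 ratio was -0.04, and the antioxidant list lay lower. Of 71 nuclear-encoded respiratory chain genes 40 were lower, with a median of -0.02 (-0.03 to -0.01) and percentile 46.0; this sign turned under 2 of 14 alternatives, TMM scaling among them. In none of the 71 did the higher value stand 25% above the lower, and the widest was Cox7a2l at 377 (370.1 to 383) against 319 (312 to 325) CPM. The tricarboxylic acid cycle list had a median of -0.05 (-0.08 to -0.01) (14 of 19 lower, percentile 26.6), with Idh3g at 107 (104 to 111) against 93.9 (90.4 to 97.53) CPM. Fatty acid oxidation and lipid uptake stood at -0.06 (-0.10 to -0.03) (15 of 19 lower, percentile 16.5), with Lpl, lipoprotein lipase, at 158 (154 to 162) against 131 (127 to 135) CPM and the scavenger receptor gene Cd36 at 178 (173 to 182) against 148 (144 to 153) CPM. The pentose phosphate list stood at 0.01 (-0.04 to 0.03) (percentile 75.8), a sign that turned under 6 of 14 alternatives. Antioxidant genes had a median of -0.10 (-0.13 to -0.06) (10 of 16 lower, percentile 1.43): Gpx1 was lower at 622 (613 to 630.1) against 526 (518 to 534) CPM and Gpx4 higher at 152 (148 to 156) against 181 (176 to 186) CPM. For cKO cells with Gm28438 alone, the antioxidant median was 0.01 (-0.04 to 0.07) against fl/fl cells with mt-Nd3 alone. Against fl/fl cells with Gm28438 alone it was -0.14 (-0.20 to -0.06). NADPH oxidase genes had a median of 0.02 (-0.00 to 0.05) (percentile 75.5), a sign that turned under 1 alternative.

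Interferon-response genes showed the widest shift among the lists. All 16 measured members were higher in cKO microglia-like cells, each by at least 25%, with a median log2 ratio of 1.39 (1.31 to 1.47), above all 10000 random lists. Isg15, a ubiquitin-like modifier, measured 21.5 (19.9 to 23.1) against 105 (102 to 109) CPM, and Irf7, a transcription factor of the interferon response, 22.4 (20.8 to 24.1) against 82.3 (79.0 to 85.7) CPM. Oasl2 stood at 12.9 (11.8 to 14.2) against 47.3 (44.8 to 49.9) CPM and Ifit3 at 19.3 (17.8 to 20.8) against 61.0 (58.2 to 63.9) CPM. The abundant members shared the direction: Ifi27l2a at 1624 (1609.9 to 1637) against 3246 (3226 to 3267) CPM, Ifitm3 at 287 (281 to 293) against 844 (833 to 854) CPM and Cxcl10 at 465 (458 to 472) against 752 (742 to 762) CPM. The list was higher in each of the 7 microglia-like clusters, with medians from 1.11 to 2.48. Most of the fl/fl microglia-like cells lay in clusters 4, 2 and 3 (684, 458 and 450 cells) and most of the cKO cells in clusters 5, 4 and 1 (441, 402 and 330).

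**Figure D2:**
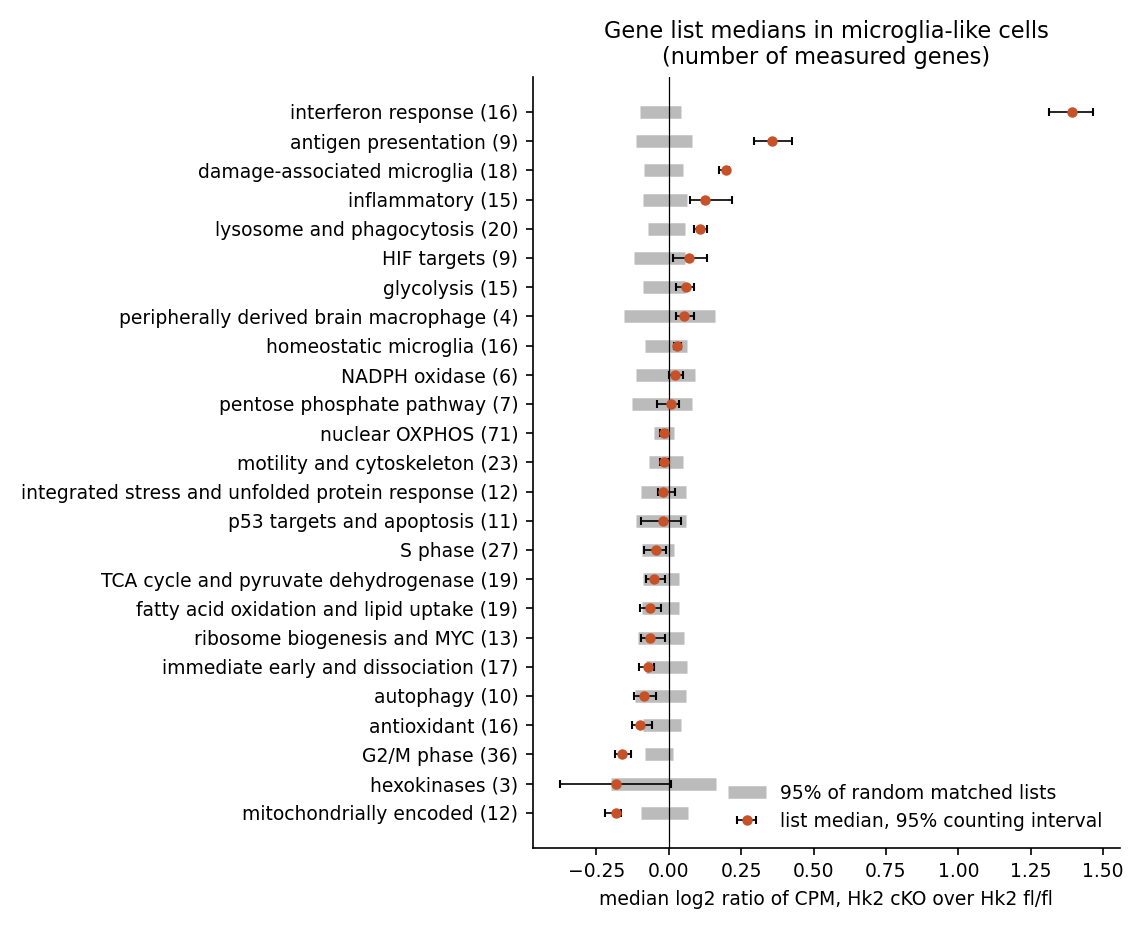
Median log2 ratio of CPM, Hk2 cKO over Hk2 fl/fl, for 25 gene lists in microglia-like cells (points, with 95% counting intervals), against the central 95% of medians of random lists matched on expression (grey bars). The interferon response list stood at 1.39 and the antigen presentation list at 0.36; the hexokinase, pentose phosphate, OXPHOS, NADPH oxidase, S phase, peripheral macrophage, motility, stress, p53 and immediate early medians turned sign under at least 1 alternative.

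Most antigen presentation genes were higher too. The antigen presentation list had a median of 0.36 (0.29 to 0.43), with 7 of 9 measured genes higher, above all random lists and higher in all 7 clusters. H2-K1 measured 669 (661 to 678) against 1027 (1015 to 1039) CPM, H2-D1 896 (885 to 906) against 1333 (1319 to 1346) CPM, the class I light chain gene B2m 1809 (1795 to 1824) against 2555 (2537 to 2574) CPM and the peptide transporter gene Tap1 54.9 (52.4 to 57.5) against 85.0 (81.6 to 88.4) CPM. The class II genes Cd74 and H2-Ab1, picked after their values were seen because they were the 2 lower members, had log2 ratios of -0.12 and -0.15.

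Most genes of the inflammatory list were higher. Of 15 measured members 11 were higher, 7 of them by at least 25%, with a median of 0.12 (0.07 to 0.22) at percentile 99.95. Tnf measured 467 (459 to 474) against 777 (767 to 787) CPM, Ccl2 1436 (1423 to 1449) against 2368 (2350.0 to 2386) CPM, Ccl4 2272 (2256 to 2289) against 3634 (3612 to 3656) CPM, Ccl3 1526 (1513 to 1539) against 2066 (2049.8 to 2083) CPM and Il1b 266 (261 to 272) against 399 (392 to 406) CPM. Lower were Cxcl2, Ptgs2, Il6 and Tnfaip3, picked after their values were seen because they went the other way, with log2 ratios of -0.28, -0.15, -0.14 and -0.12. The list was higher in 6 of 7 clusters, and Il1b and Ccl4 were each lower in 2 of 7. Cluster 5, led by Ccl7, Rcan1, Il1b, Cxcl2, Tnf and Ccl4 and singled out after its values were seen, held 13.6% (12.3 to 15.02) of fl/fl and 21.8% (19.997 to 23.6) of cKO microglia-like cells. The list median rested on which members counted as measured and on the cells kept, and reached 0.30 with the stricter cell filter.

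**Figure D3:**
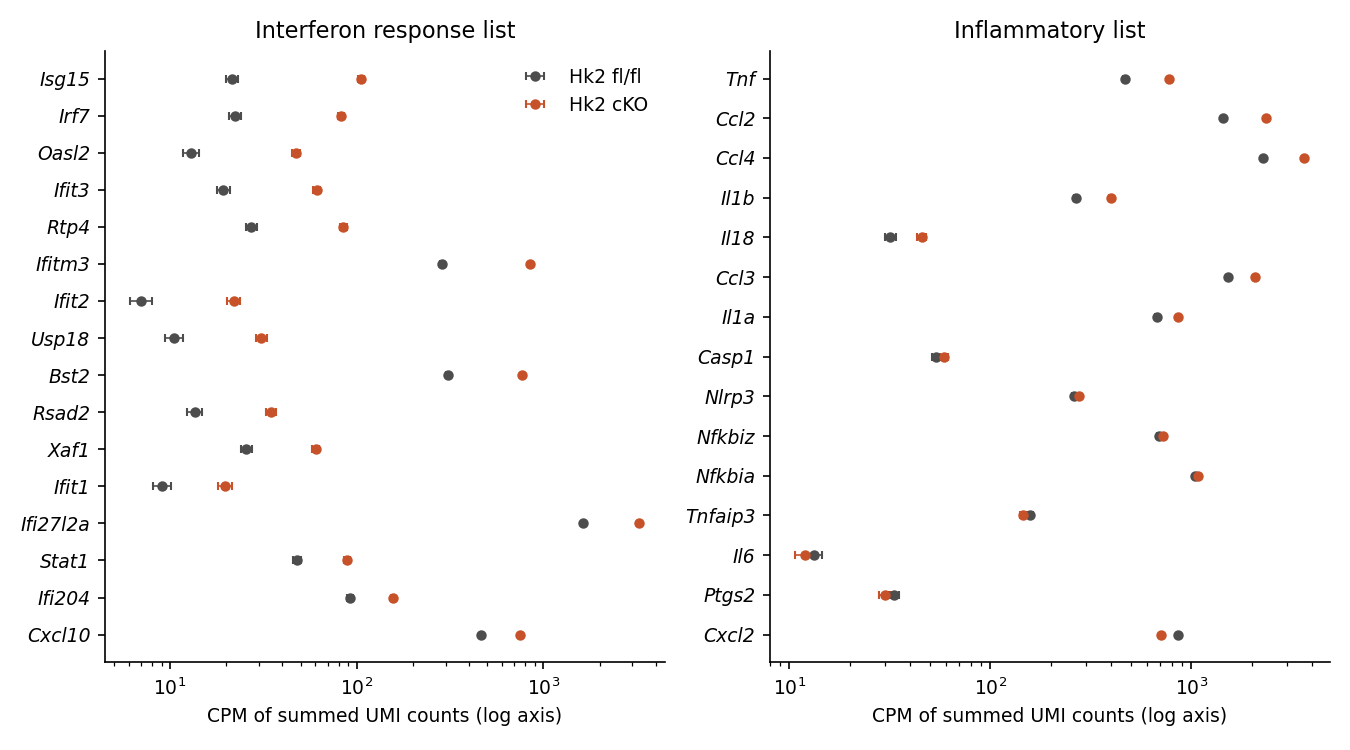
CPM (log axis) of each measured gene of the interferon response (left) and inflammatory (right) lists in summed microglia-like cells of the Hk2 fl/fl (grey) and Hk2 cKO (orange) libraries, with exact 95% Poisson intervals. All 16 interferon genes and 11 of 15 inflammatory genes lay higher in the cKO library.

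Genes of the damage-associated microglial state were mostly higher. Of 18 measured members 12 were higher and 6 lower, with a median of 0.20 (0.17 to 0.21), above all random lists; the list was higher in 5 of 7 clusters. Csf1 measured 31.4 (29.6 to 33.4) against 48.4 (45.9 to 51.0) CPM, the integrin gene Itgax 19.3 (17.8 to 20.8) against 28.3 (26.4 to 30.3) CPM and Cst7 15.2 (13.9 to 16.6) against 20.3 (18.7 to 22.0) CPM; Fabp5, a fatty acid binding protein gene, was lower at 14.2 (12.96 to 15.6) against 7.55 (6.58 to 8.62) CPM. The abundant Ctsd and Cd9 were higher at 5359 (5334 to 5384) against 6134 (6106 to 6163) CPM and 1350.5 (1338 to 1363) against 1594 (1579 to 1608) CPM. Lysosomal and phagocytic genes had a median of 0.11 (0.09 to 0.13) (17 of 20 higher, percentile 99.96) and were higher in all 7 clusters, led by the protease gene Ctsl at 656 (647 to 664) against 867 (856 to 878) CPM and by Grn at 1281 (1269 to 1293) against 1552 (1537 to 1566) CPM. This list shares Ctsb, Ctsd, Cd68 and Axl with the damage-associated list.

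Homeostatic microglial identity genes were nearly level as a list, with Crybb1 higher and Cx3cr1, whose locus carries the Cre driver, lower. Their median was 0.03 (0.02 to 0.04) (10 of 16 higher, percentile 86.7). Sall1, a transcription factor gene of microglial identity, measured 60.8 (58.2 to 63.5) against 66.6 (63.7 to 69.7) CPM; Crybb1 was higher at 16.6 (15.3 to 18.1) against 25.6 (23.8 to 27.6) CPM. P2ry12 and Tmem119, picked after their values were seen because they are widely used markers, had log2 ratios of -0.02 and 0.07. The list of peripherally derived brain macrophages had 4 measured genes with a median of 0.05 (0.02 to 0.09) (percentile 82.9), which turned sign under 2 of 14 alternatives: Apoe was at 567 (558 to 575) against 721 (711 to 731) CPM and Lyz2 at 564 (556 to 572) against 487 (479 to 495) CPM.

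Dividing cells were somewhat fewer in the cKO library by G2/M genes, and less clearly so by S-phase genes. After thinning to 5000 UMIs, 29.1% (27.2 to 31.0) of 2282 fl/fl and 23.7% (21.8 to 25.7) of 1847 cKO microglia-like cells were G2/M-positive, with UMIs of at least 3 of 12 genes; 223 and 178 shallower cells were left out. Unthinned, the shares were 43.3% and 35.7%. S-positive cells were 22.2% (20.5 to 23.9) and 20.6% (18.8 to 22.5), and 38.6% and 36.9% unthinned. Among endothelial-, monocyte- and neutrophil-like cells without UMIs of 4 microglial markers, 6 of 82 fl/fl and 6 of 107 cKO cells had UMIs of at least 3 G2/M genes, unthinned, at median depths of 5608 and 5931 UMIs. With or without marker UMIs, 59 of 210 fl/fl and 46 of 214 cKO cells of these classes had UMIs of at least 3 of the genes. The median log2 ratio of the G2/M list was -0.95 in endothelial-like, -2.01 in monocyte-like and -0.73 in neutrophil-like cells. Lower G2/M values were thus not confined to microglia-like cells, though these classes also hold microglial RNA. In microglia-like cells the G2/M difference widened to 41.7% against 32.2% when 2 of 12 genes were asked for. It shrank to 16.2% against 14.7% when 5 of 12 genes were asked for, and to 18.4% against 16.7% at 2500 UMIs, with overlapping intervals in each. The S difference widened to 35.9% (34.0 to 37.9) against 31.5% (29.3 to 33.6) with 2 of 12 genes and vanished at 2500 UMIs (11.3% and 11.4%). In the groups by mt-Nd3 and Gm28438, the G2/M-positive share at 5000 UMIs was 27.1% (24.8 to 29.5) in cKO cells with Gm28438 alone. In fl/fl cells it was 30.3% (27.2 to 33.5) with mt-Nd3 alone and 32.8% (27.5 to 38.4) with Gm28438 alone. Both fl/fl intervals overlapped that of the cKO cells.

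**Figure D4:**
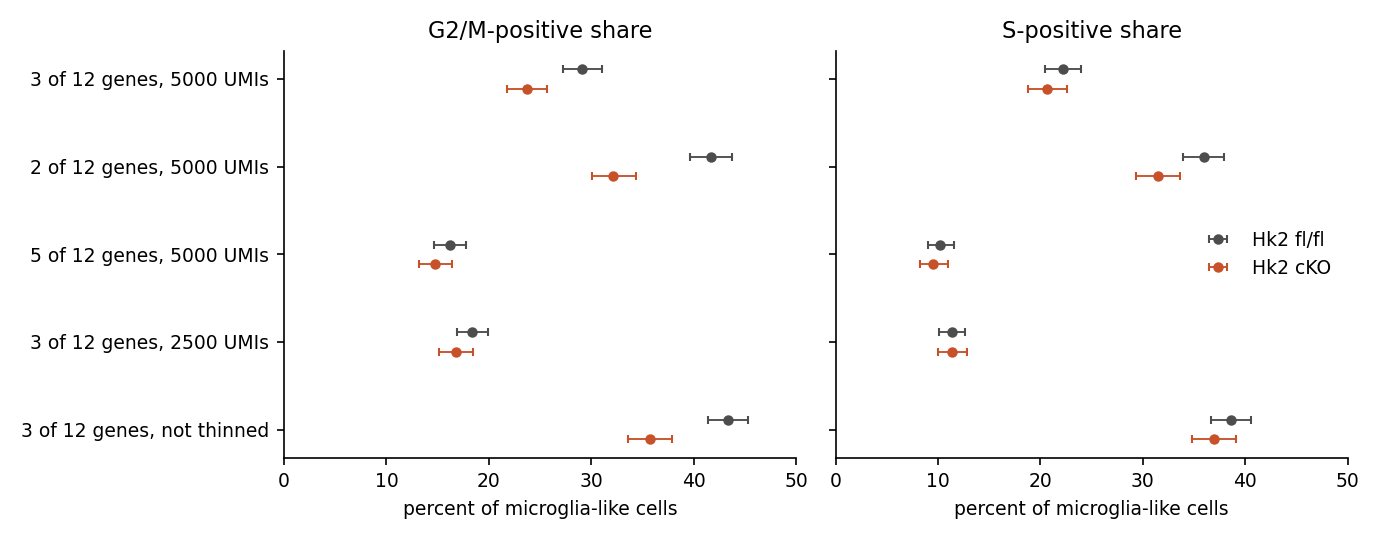
Percent of microglia-like cells that were G2/M-positive (left) or S-positive (right) in the Hk2 fl/fl (grey) and Hk2 cKO (orange) libraries, with exact 95% Clopper-Pearson intervals, under 5 settings of depth and of the genes asked for. The G2/M share was lower in the cKO library under each, from 41.7% against 32.2% with 2 of 12 genes, through 29.1% against 23.7% with 3 of 12 at 5000 UMIs, to 16.2% against 14.7% with 5 of 12.

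Levels of the G2/M genes had the same direction. Of 36 measured genes 32 were lower, with a median of -0.16 (-0.19 to -0.13), below all random lists. Mki67, a proliferation marker gene, measured 129.9 (126 to 134) against 100.5 (96.8 to 104) CPM, Birc5 147 (143 to 151) against 128 (124 to 132) CPM, Cenpa 129 (125 to 133) against 107 (103 to 111) CPM and Ube2c 164 (159.7 to 168) against 146 (142 to 151) CPM. The list was lower in 4 of 7 clusters and higher in 3, and its median was -0.26 with the stricter cell filter. Under that filter a cluster of 223 fl/fl and 328 cKO cells, with Cdk1 and Ube2c among its leading genes, lost its microglia-like name. The -0.26 therefore leaves out cells with G2/M genes, more of them from the cKO library. The size of the list median also depended on which fl/fl cells were compared. For cKO cells with Gm28438 alone, the median was -0.000682 against fl/fl cells with mt-Nd3 alone and -0.26 against those with Gm28438 alone. In clusters 3, 4 and 5 the G2/M-positive shares were 7.65%, 12.2% and 10.7% in the fl/fl and 3.15%, 4.60% and 6.81% in the cKO library. In clusters 1 and 2 they were nearly level, at 25.7% and 36.7% against 24.2% and 36.1%. In clusters 0 and 8, which G2/M genes define, they were 97.1% and 97.7% against 97.96% and 98.3%. The S phase list had a median of -0.04 (-0.09 to -0.01) (17 of 27 lower, percentile 46.4), with Dtl at 18.7 (17.2 to 20.2) against 15.1 (13.7 to 16.6) CPM and Pcna at 188 (183 to 192) against 188 (183 to 193) CPM, and turned sign under 1 of 14 alternatives. Its sign also depended on the fl/fl group. For cKO cells with Gm28438 alone, the S phase median was 0.12 against fl/fl cells with mt-Nd3 alone and -0.47 against those with Gm28438 alone.

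Mitochondrially encoded protein-coding genes were mostly lower in the cKO library, with a median of -0.18 (-0.22 to -0.17), 10 of 12 lower, below all random lists and lower in all 7 clusters. This list leaves out the mitochondrial ribosomal RNA genes. All mitochondrial genes together took 3.15% of the fl/fl and 2.99% of the cKO sums. mt-Nd1 measured 3772 (3751 to 3793) against 2846 (2827 to 2866) CPM and mt-Nd4 3686 (3665 to 3707) against 2941 (2922 to 2961) CPM; mt-Atp8 was higher at 157 (153 to 162) against 194 (189 to 199) CPM. mt-Nd3 measured 145 (141 to 149) against 1.84 (1.38 to 2.41) CPM. Its reads can be shared with a nuclear copy, Gm28438, which matches it over 345 bases with 1 mismatch, so the level of either gene is uncertain. Gm28438, picked after its values were seen, measured 59.7 (57.1 to 62.4) and 277 (271 to 283) CPM, and the pair together 204 and 279 CPM. Leaving mt-Nd3 out gave a list median of -0.18.

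**Figure D5:**
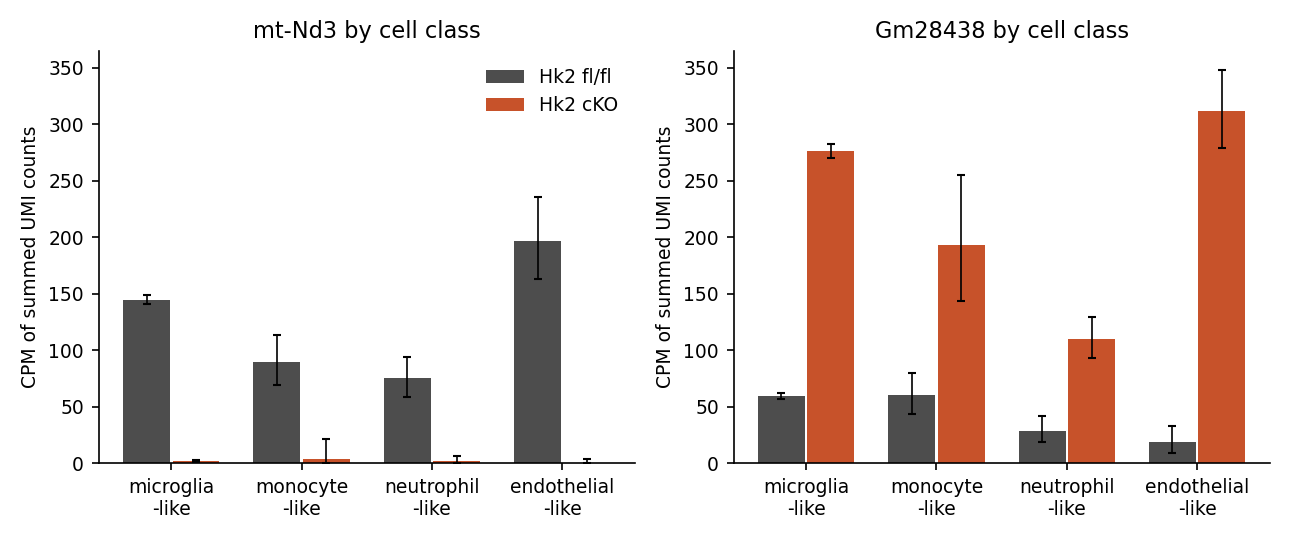
CPM of mt-Nd3 (left) and of its nuclear copy Gm28438 (right) in summed counts of each named class in the Hk2 fl/fl (grey) and Hk2 cKO (orange) libraries, with exact 95% Poisson intervals. In microglia-like cells mt-Nd3 stood at 145 against 1.84 CPM and Gm28438 at 59.7 against 277 CPM; reads can be counted to either gene.

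The remaining lists differed little. Motility and cytoskeleton genes had a median of -0.02 (-0.03 to -0.00) (percentile 41.9), with the intermediate filament gene Vim lower at 539 (531 to 547) against 392 (385 to 399.8) CPM, and turned sign under 1 alternative. Ribosome biogenesis and MYC genes stood at -0.07 (-0.10 to -0.01) (percentile 16.7), with Odc1 at 62.8 (60.1 to 65.5) against 72.3 (69.2 to 75.5) CPM. The integrated stress and unfolded protein response list stood at -0.02 (-0.04 to 0.02) (percentile 50.5), with Herpud1 at 334 (328 to 340.1) against 294 (288 to 301) CPM, and turned sign under 2 alternatives. The p53 and apoptosis list stood at -0.02 (-0.10 to 0.04) (percentile 57.4), with Cdkn1a at 581 (573 to 589) against 719 (709 to 729) CPM, and turned sign under 3. Autophagy genes stood at -0.09 (-0.12 to -0.04) (percentile 9.91), with Gabarapl1 at 41.8 (39.6 to 44.1) against 34.4 (32.3 to 36.6) CPM. Immediate early and dissociation genes stood at -0.07 (-0.10 to -0.05) (percentile 4.49), with Klf2 at 557 (549 to 565) against 412 (405 to 419) CPM and Klf6 at 1092 (1081 to 1104) against 838 (828 to 849) CPM, and turned sign under 1. The sex genes stood at -0.07 (-0.14 to -0.01) (percentile 32.4) and turned sign under 1; Ddx3y, on the Y chromosome, was at 108 (105 to 112) against 99.7 (96.1 to 103) CPM, and Xist gave 4 and 6 UMIs.

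Across single genes the libraries were close. Of 7816 measured genes 94.3% had a higher value less than 25% above the lower. Among genes with a mean of at least 50 CPM and intervals that do not overlap, without mitochondrial, ribosomal protein, haemoglobin and sex genes and models named Gm or Rik, the 12 highest ratios belonged to Isg15, Irf7, Slfn5, Rtp4, Ifitm3, Bst2, Lgals3bp, CT010467.1, Phf11b, Rnf213, Ifi27l2a and Ifi207, with log2 ratios from 2.24 to 0.92. Of these Slfn5 measured 23.1 (21.5 to 24.8) against 80.7 (77.5 to 84.1) CPM, Lgals3bp 167 (162 to 171) against 378 (371 to 385) CPM and the ribosomal RNA gene CT010467.1 90.8 (87.5 to 94.1) against 198 (193 to 203) CPM. Among the same genes the 12 lowest belonged to Hk2, Cx3cr1, Ifi27, Trmt112, Cnn2, Lsp1, Mir703, Vim, Ptger4, Klf2, Anxa2 and Clec4a2, with log2 ratios from -1.91 to -0.39. Ifi27 stood at 75.7 (72.8 to 78.7) against 49.9 (47.4 to 52.6) CPM, Trmt112 at 126 (122 to 130.0) against 84.7 (81.4 to 88.1) CPM, the actin-binding Cnn2 at 61.1 (58.5 to 63.9) against 41.4 (39.1 to 43.8) CPM and Lsp1 at 169 (164 to 173) against 117 (113 to 121) CPM.

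Markers of other cell types were present at low levels within the microglia-like sums. Endothelial markers summed to 673 CPM in the fl/fl and 706 CPM in the cKO library, neutrophil markers to 170 and 157, monocyte markers to 115 and 137, and border macrophage markers to 118 and 94.4. B cell markers summed to 180 and 126 CPM, dendritic cell markers to 34.8 and 37.1, oligodendrocyte markers to 36.7 and 38.0, mural markers to 26.8 and 23.1, and astrocyte markers to 21.4 and 27.2. Of the B cell sums, Igkc gave 61.7 CPM in the fl/fl and 0 in the cKO library, and 1 fl/fl cell held 2009 of its 2045 UMIs. Ependymal and choroid markers summed to 18.0 and 6.37, precursor markers of oligodendrocytes to 6.61 and 5.11, neuroblast markers to 3.83 and 3.096, neuron markers to 3.53 and 3.97, erythroid markers to 2.54 and 0.557, T cell markers to 1.51 and 2.16, fibroblast markers to 0.392 and 0.487 and NK cell markers to 0.272 and 0.313. The microglial markers summed to 34358 and 37682 CPM.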

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

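Tests chosen only after the result was seen were those of mitochondrial RNA yield, of mt-Nd3 in marker-free cells, of the interferon list with intervals and monocyte-like cells, of depth, of microglia-like barcodes left out and of free RNA.

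mt-Nd3 was almost absent from cKO microglia-like cells (53 UMIs against 4794), while Gm28438, a gene outside the named ones, was higher at 277 CPM against 59.7 CPM. Against loss of Hk2 in microglia as the cause, mt-Nd3 was lower in endothelial-like cells too (0 against 117 UMIs, upper bound of the log2 ratio -5.76), a class that also carries microglial RNA, and in pooled endothelial-, monocyte- and neutrophil-like cells without microglial marker UMIs (0 against 23 UMIs, upper bound -3.27). A lower yield of mitochondrial RNA would need the other mitochondrially encoded protein-coding genes to be far lower, and their median was -0.18. A mitochondrial lineage or strain variant is a candidate explanation, with log2 ratios of -7.63, -4.53 and -4.21 in endothelial-, neutrophil- and monocyte-like cells (highest upper bound -2.0001), and so are reads counted to the nuclear copy, which is 99.7% identical over 345 bases. The 1 mismatch lies at base 3 of mt-Nd3, and a variant and reads counted to the copy need not exclude each other. No base difference between the libraries was examined, since counts hold no sequence.

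In the other named classes, which also hold microglial RNA, the summed CPM of the interferon response list was 6121 in the cKO against 3356 in the fl/fl library in endothelial-like, 8384 against 5527 in monocyte-like and 4158 against 2084 in neutrophil-like cells. Microglial content was far from equal in monocyte-like cells, with 89.0 CPM of the 4 microglial markers in the cKO against 1112 CPM in the fl/fl library. Without microglial marker UMIs the interferon sum was 4978 against 2846, 8281 against 8148 and 1659 against 1514, nearly level in the latter 2 classes. The tables argue against a small group of responding cells as the whole source, since the list's median stayed at 1.48 without the interferon-led cluster of 27 fl/fl and 95 cKO cells found at resolution 1.5. Free RNA from the cells of that cluster in other droplets was not examined. For a signal across brain cell types, the test set beforehand was met in cells without microglial marker UMIs, with a lower median of 1.08 in neutrophil-like (31 and 58 cells, interval -0.02 to 1.42) and 3.57 in endothelial-like cells (8 and 20 cells). A stricter form with intervals and monocyte-like cells (43 and 29 cells, median -0.0319, interval -0.62 to 0.07) was not met, and over the 3 classes pooled, whose mix differs between the libraries, the median was -0.52, so a signal across cell types is left open, and free microglial RNA may account for much of the class values. Cre activity and loss of Hk2 go together here, because the fl/fl mice are described without the Cre driver. It is also not known whether the fl/fl mice received tamoxifen, so a difference in that treatment cannot be told apart.

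The G2/M-positive share in the cKO library minus that in the fl/fl library was -5.38 percentage points. Loss of cycling barcodes in the cell filter is not settled by the share with every barcode kept (-5.99 points), since that counted 2302 and 1858 cells against 2282 and 1847; among left-out barcodes that then clustered as microglia-like, the 76 of the cKO library held 627 (531 to 736) CPM of the 12 genes against 830 (820 to 841) in kept cKO cells, and counting the 67 of the fl/fl library as negative would leave its share at 28.3%, which argues against loss among these, while left-out barcodes of other clusters stay open. The tables argue against a difference in depth as the whole cause, since the cKO cells were the deeper ones (median 12055 against 10193 UMIs) and depth alone would give them the higher share, yet the difference was -7.61 points without thinning; that of -1.63 points at 2500 UMIs decides nothing on this, because thinning further lowers both shares. For free RNA, the first test was met: the 12 genes' summed CPM in pooled other cells without microglial marker UMIs was 358 fl/fl against 261 cKO (upper bound of the log2 ratio -0.15). As 149 of the 164 fl/fl UMIs lay in 6 of 82 cells, cells with fewer than 3 of the genes were read next. The marker-free cells (37.1 CPM fl/fl) decide nothing, being chosen for little microglial RNA. All such fl/fl cells of the 3 classes, with or without marker UMIs, held 67.9 (53.6 to 84.8) CPM against 122 (117 to 129) in microglia-like cells. In the cKO library the values were 56.0 (44.1 to 70.1) and 86.2 (81.6 to 91.0) CPM. This argues against free RNA as the whole source of UMIs in cells below 3 genes and leaves a part open. It does not decide whether free RNA made the difference between the libraries, because cells with at least 3 of the genes, 59 of 210 fl/fl cells of these classes, were left out.

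Barcodes above 10% mitochondrial UMIs, which the comparisons leave out, were 11.3% (10.1 to 12.6) of cKO and 7.80% (6.88 to 8.80) of fl/fl barcodes.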

How the results depend on the processing

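The doublet-rate alternative and those without mt-Nd3 or Cx3cr1 were chosen after seeing the data. Under its 12 alternatives Hk2 stayed lower (-1.94 to -1.78), moving by more than its counting error to -1.81 (per-cell means), -1.78 (thinned sums) and -1.82 (5 CPM added). Over 16 alternatives the 26 list medians gave 366 values, 319 nearer the first value than its counting error and 47 farther; of 858 values of named genes 720 and 138. The interferon median stayed at 1.19 or above (1.29 with per-cell means, 1.21 thinned, 1.19 with 5 CPM added). The inflammatory median was 0.23 without mitochondrial and ribosomal genes, 0.24 at 50 CPM, 0.30 with the strict filter (1000 genes, 5% mitochondrial), 0.24 at the doublet rate and 0.24 in noncycling cells; in part this follows from which members are measured (12 at 50 CPM). The G2/M median was -0.26 (strict, where a cluster with G2/M genes among its leading genes lost its name), -0.20 (doublet rate) and -0.59 (noncycling, where cells with these genes are removed by construction and 12 of the 36 genes stay measured). S phase was 0.00403 (per-cell means) and -0.10 (noncycling, 16 of 27 genes measured); OXPHOS 0.00340 (TMM), 0.00543 (per-cell means), -0.0483 (strict) and -0.0568 (noncycling); homeostatic 0.0471 (TMM) and 0.0114 (strict); damage-associated 0.17 (doublet rate). The microglia-like share differed (cKO minus fl/fl) by -2.71 points with every barcode, -7.41 (strict) and 1.54 (resolution 1.5), since naming changed for a cluster in the last 2. The G2/M share differed by -9.51 (2 of 12), -1.44 (5 of 12) and -1.63 (2500 UMIs) and the S share by -4.48 (2 of 12). Elsewhere the cause was not tested. TMM scaling moved the median of all measured genes from -0.04 to -0.02. No paired analysis was possible because each genotype has 1 library. Depth limits low genes: 1 CPM is 33.1 UMIs in the fl/fl and 28.7 in the cKO sums.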

Other observations

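The test against 1 common mix of mt-Nd3 and Gm28438 was chosen after the share of cells with both genes had been seen.

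Immunoglobulin genes, chosen after their values were seen, lay almost wholly in single fl/fl microglia-like cells: Igkc gave 2045 UMIs (2009 in 1 cell), Igha 723 (708 in 1 cell) and Jchain 216 (205 in 1 cell), against 0, 0 and 2 UMIs in cKO microglia-like cells. Plac8 and Ccr1, also chosen afterwards, went opposite ways in microglia-like cells. Plac8, a gene of monocytes among other cells, was at 5.98 (5.17 to 6.87) CPM in the fl/fl and 32.7 (30.7 to 34.9) CPM in the cKO library, and the chemokine receptor gene Ccr1 at 55.2 (52.7 to 57.8) and 29.3 (27.3 to 31.3) CPM. Within 10 Mb of Cx3cr1, 6 of 63 measured genes (9.52%, 3.58 to 19.6) had a higher value at least 25% above the lower, and within 10 Mb of Hk2 1 of 77 (1.30%, 0.0329 to 7.02), against 5.67% of all measured genes.

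A hypothesis from these data is that the fl/fl library pools mice of 2 mitochondrial types. Of 736 fl/fl microglia-like cells with at least 4 UMIs over the pair, 424 held mt-Nd3 alone, 121 Gm28438 alone and 191 (26.0%, 22.8 to 29.3) both. The bound set beforehand, under 20%, was missed, while 1 mix common to all cells would give 84.4%, so the share was far below a common mix, which may reflect separate types. Of 894 cKO cells, 854 held Gm28438 alone and 40 both. A C57BL/6J against C57BL/6N difference was left undecided by Nnt, with a log2 ratio of 0.14 over all kept cells at 1.57 and 1.82 CPM, where the 3' tag may lie outside the part that C57BL/6J lacks.

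If the types mark different mice, they show how far mice of 1 genotype can differ; this was examined over 26 lists and 3 comparisons after the types had been seen. Between 305 fl/fl cells with Gm28438 alone and 870 with mt-Nd3 alone (at least 2 UMIs; median depths 12248 and 12674), the list medians were 0.64 for S phase (27 of 27 genes higher), 0.43 for ribosome biogenesis and MYC, 0.22 for G2/M, 0.21 for glycolysis, -0.25 for homeostatic genes and 0.14 (0.01 to 0.28) for the interferon response. The median was also 0.25 (0.21 to 0.33) for inflammatory, 0.16 for antioxidant and -0.13 for lysosomal genes. In 20 of 26 lists this median was larger in size than that between the libraries. The other 6 were the interferon response, antigen presentation, damage-associated, mitochondrially encoded, hexokinase and NADPH oxidase lists. Among the 20, the counting interval within the fl/fl library spanned both signs for the HIF, peripheral macrophage, motility and p53 lists. The fl/fl groups also hold fewer cells than the libraries, so their medians carry more counting error. For 1435 cKO cells with Gm28438 alone, the interferon median was 1.58 against the mt-Nd3 group and 1.33 against the Gm28438 group, the G2/M median -0.000682 and -0.26, the S phase median 0.12 and -0.47 and the glycolysis median 0.08 (0.04 to 0.12) and -0.10 (-0.15 to -0.01), and in 12 of 26 lists, the last 2 among them, the sign depended on the fl/fl group. Hk2 stood at 169 and 149 CPM in the fl/fl groups and 39.5 CPM in the cKO group, and Cx3cr1 at 1264, 1249 and 669.6 CPM. So differences between animals may account for shifts of the size seen between the libraries in those 20 lists, less clearly for the HIF, peripheral macrophage, motility and p53 lists. The single interferon value within the fl/fl library (0.14) was smaller than the shift between the libraries. However, 1 value cannot bound how far animals differ, and the test set beforehand on it (interval 0.01 to 0.28) decided nothing.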
